A study of Mus musculus with 4 samples.

How the data were processed

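Splenic CD3+ T cells of 4 female F1 mice, bred from C57BL/6 mothers with a heterozygous Xist deletion and Mus musculus castaneus fathers, were enriched on columns and cultured for 48 hours with plate-bound anti-CD3 at 1 µg/ml and soluble anti-CD28 at 10 µg/ml in the presence of 2.5 µM IMD-0354, per the labels. The 4 samples are labelled as biological replicates and form 1 group. Total RNA libraries were made with a stranded kit that removes ribosomal RNA, per the labels' protocols.

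The authors deposited 2 tables of 49671 genes. The first, deposited as counts, holds whole-number read counts per gene for the C57BL/6 and the Castaneus allele of each replicate, which the authors did not normalize, per the file headers. The second holds RPKM values of both alleles together, computed by the authors, and which total they were scaled by is not given in the sources used here. STAR 2.7.1a, featureCounts (with no version) and the mm10 genome are named in the submitters' processing notes. How reads were assigned to an allele, which variants were used, whether duplicates were removed and whether strand was used in counting are not given in the sources used here. Of the values above 0, 60.0% to 68.2% were even per replicate, as if both reads of a pair were counted. All 37 mitochondrial genes have 0 allelic reads, as have genes on scaffolds, so the planned check of maternal mitochondrial RNA was void. Gene positions and biotypes came from GENCODE M21 for the same build, in which 49412 of the gene IDs were found, 49375 of them on the chromosome the files name. In the deposited files, 26 symbols read as calendar dates, none of which is named in the text.

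Allelic reads numbered 30539711 to 34992012 per replicate, and RPKM values correlated between replicates with r of 0.970 to 0.985 across 11453 genes. Reads were clumped. Among autosomal genes with 20 to 39 allelic reads, the share read from 1 allele only was 36.4%, 84.2%, 45.2% and 13.5% in replicates 1 to 4. If each clump is 1 molecule and both alleles are equally active, this corresponds to about 11.4, 22.6, 13.0 and 7.19 reads per molecule. Equal activity does not hold for all of these genes. Those seen from 1 allele in both of 2 replicates showed the same allele in 80.2% of 434 cases, where equal alleles give 50%. These estimates may therefore be too high. Binomial intervals on reads are then too narrow, and the main tests rest on the spread between replicates.

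For the tests of allelic ratio, genes needed a mean of at least 20 allelic reads per replicate and a mean of at least 1 RPKM, which left 304 X genes and 10268 autosomal genes. Of 348 X genes with at least 1 RPKM, 44 had too few allelic reads. The 2 allele counts of each replicate were fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with the replicate as a block, since both alleles were read in the same animal, and an allele term. The library size of an allele was its autosomal total. The ratio of Castaneus to C57BL/6 was tested against 0.1 for X genes, which is a share of 9.09%, and against 1 for autosomal genes, two-sided, with Benjamini-Hochberg adjustment over X or autosomal genes and an FDR of 5%. A gene is called above or below when it passes, and otherwise is undecided. Lists of X genes were compared with the other X genes by Fisher's exact test on the calls and by camera (limma 3.58.1). Camera ranked genes by the allele term against a ratio of 1, not 0.1. Differences between animals were tested per gene with a chi-square test, or 100000 random tables where an expected count was under 5. Correlations used 100000 permutations. List medians of RPKM were ranked among 10000 random lists of the same size from genes with a mean of at least 0.1 RPKM. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

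The tests were tried on simulated counts with the real means, library sizes and reads per molecule, in 10 simulations with 200 genes changed on the autosomes and the X together. The spread of molecule numbers was set to the same fixed value for all genes and not taken from the data. Mapping bias of single genes and allele shares particular to an animal were not simulated, so the rates hold for these settings only. On the autosomes 72.7% of the 2-fold and 20.9% of the 1.5-fold changes were recovered among 10268 genes and 0% of unchanged genes were called. Among 304 X genes, 79.5% of those with a true ratio of 0.3 and 85.0% of those with 0.6 were called above, 2.5% of those at 0.1 were called above, and 95.7% of those at 0.005 were called below.

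The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Xist and Tsix, members of the X lists called above and up to 4 per list called below with the most reads, the 15 X genes above with the highest Castaneus share that exceed the null in 4 of 4 replicates, the 5 below with the most reads, called imprinted genes, the 5 autosomal genes per direction with the largest absolute log2 ratio (called, the same direction in 4 of 4 replicates, at least 50 reads), the 3 highest and the lowest members of each expression list, and the 5 X genes with the smallest adjusted p between animals. Values of a few genes that the rule takes are left out of the text. Other genes named in the text were chosen after their values were seen, among them Slc10a3, Mtcp1, Atp7a, Trmt2b, Mcts2, Ftx, Firre and the genes named in the closing section. The alternatives were no replicate block, equal library sizes, TMM factors, DESeq2 1.42.0 size factors and its Wald test, minimums of 10 or 50 reads, no RPKM minimum, null ratios of 0.05 and 0.2, adjustment over all genes, calls per replicate by binomial limits, other summaries of the X share, and leaving out each replicate. The fit has the block as its main form because the design pairs the alleles within an animal. Reads divided by the reads per molecule, the exclusion of doubtful genes and the permutation of list medians were added after the data were seen.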

Results

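RNA was sequenced from splenic CD3+ T cells of 4 female hybrid mice, 1 library per mouse, all in 1 group. The cells had been cultured for 48 hours with antibodies against CD3 and CD28, which stand in for antigen and costimulation, in the presence of 2.5 µM IMD-0354, an inhibitor of the IκB kinase IKKβ that keeps NF-κB transcription factors in the cytoplasm. Each mouse had a C57BL/6 mother that carried a deletion of Xist on 1 X chromosome and a Mus musculus castaneus father. Xist, the long noncoding RNA that coats and silences the X it is made from, can then act only on the paternal X of daughters that inherit the deletion, so that reads of X genes from the Castaneus allele measured the inactive X (Xi) and reads from C57BL/6 the active X. The files held gene counts per allele and RPKM values of both alleles together. Allelic reads numbered 33140517, 30539711, 34992012 and 33306767 in replicates 1 to 4. No unstimulated cells and no stimulated cells without the inhibitor are among the 4 samples, so the effect of stimulation or of the inhibitor was not tested, and the values below describe this 1 condition.

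Xist came from the paternal X in all 4 replicates. The Xist gene (ENSMUSG00000086503, X:103460366-103483254, mm10) gave 99.9% ± 0.0177 of its allelic reads from Castaneus (SD, n = 4), with 35 to 74 C57BL/6 reads per replicate, at 91.3 ± 6.38 RPKM. Tsix, the antisense partner of Xist, gave 11.3% ± 9.71 of its reads from Castaneus. The exact Clopper-Pearson 95% intervals for Xist spanned 99.9% to 99.97% over the 4 replicates, and in replicate 2 the 0 Castaneus reads of Tsix out of 24 allow a share of up to 12.5%, with 3 counts as the limit. Reads that are copies of 1 molecule are not independent, so these intervals cover counting error only. The strand setting of the counting is not given in the sources used here, so reads of the stretch that Tsix and Xist share were not separated.

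Most imprinted genes tested were higher from the parent their imprint predicts. Of 8 imprinted genes that could be tested, 7 were called on that side and 0 on the opposite side. Kcnq1ot1, a noncoding RNA made from the paternal chromosome 7, had 99.6% ± 0.204 of its reads from the paternal Castaneus allele, Plagl1, a zinc finger gene, 99.1% ± 0.178, Zrsr1 98.5% ± 2.18, Impact 96.0% ± 3.00 and Peg13 91.4% ± 3.33 (SD, n = 4). Igf2r, which encodes the receptor that clears IGF2 and is made from the maternal allele, had 1.86% ± 0.502 from Castaneus. H13, which encodes a signal peptide peptidase, passed with a small imbalance of 46.7% ± 1.39 from Castaneus (edgeR's quasi-likelihood test, adjusted p = 0.0375), and Mcts2 leaned to the side opposite to its imprint (log2 ratio -0.48) without passing (adjusted p = 0.149). Without the RPKM minimum 9 of 13 imprinted genes were called on the predicted side, and with a minimum of 10 reads as well 9 of 16, with 0 on the opposite side in both. The call of H13 was lost without the replicate block, with TMM factors or DESeq2 size factors, and without replicate 1, 2 or 4 (adjusted p = 0.132, 0.0763 and 0.118), and its adjusted p ranged from 0.0013 to 0.197 over 13 alternatives.

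The inactive X contributed a small part of X-linked RNA. Without Xist, 3.52% ± 0.341 of the allelic reads of X genes came from the Castaneus X (SD, n = 4), with 3.63%, 3.57%, 3.85% and 3.05% in replicates 1 to 4, against 49.6% ± 0.0870 of the autosomal reads. By chromosome the autosomal share ran from 46.9% ± 0.213 for chromosome 17 to 50.5% ± 0.0790 for chromosome 2, apart from chromosome 14 with 58.1% ± 1.17. The X share was lower than the autosomal share in 4 of 4 replicates, by 46.1 percentage points in the mean. A few genes supplied most of these Castaneus reads. The pseudogene Gm8172, which had almost no C57BL/6 reads, gave 20.6% of them, the histone demethylase genes Kdm5c and Kdm6a gave 13.5% and 9.45%, and the RNA helicase gene Ddx3x gave 7.14%. The exact two-sided sign-flip permutation test gave p = 0.13, which is the smallest p that 4 replicates allow. In alternatives chosen after the data were seen, the share was 2.65% without the genes whose Castaneus reads exceed their C57BL/6 reads, Gm8172 among them, and 0.931% without the genes called above the 10% ratio, and with Xist included it was 16.2%. Elf4, Cul4b and Dock11 remain in the 2.65%.

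**Figure D1:**
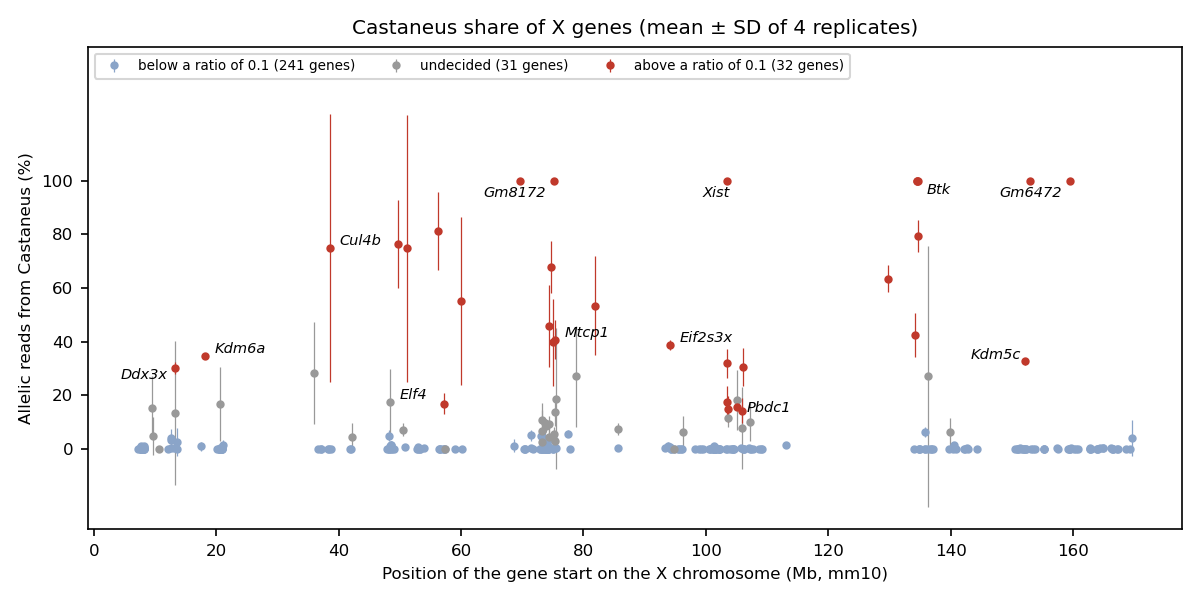
Each point is 1 of the 304 X genes tested, placed by its start on the X chromosome (horizontal axis, Mb) and by its mean share of reads from Castaneus (vertical axis, percent), with the SD of 4 replicates as a vertical line. The 241 genes called below a Castaneus to C57BL/6 ratio of 0.1 lie along the bottom, and the 32 called above it, Xist among them, are spread over the chromosome.

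Most X genes were nearly silent on the Xi, and genes of the constitutive escape list were read from it. This list holds genes known to be expressed from the inactive X in many mouse tissues. Of its 10 genes 9 were tested, and 6 of these lay above an Xi to active X ratio of 0.1. Eif2s3x, a translation initiation factor gene, had 38.7% ± 1.82 of its reads from the Xi, Kdm6a, which removes methyl groups from H3K27, 34.6% ± 0.522, Kdm5c, which removes them from H3K4, 32.6% ± 1.32, and Ddx3x 30.1% ± 2.20 (SD, n = 4). Jpx, a noncoding RNA gene beside Xist, had 17.4% ± 6.10 and Pbdc1 15.6% ± 0.972. Utp14a, with 4.88% ± 1.99, and Mid1, with 3.96% ± 6.77, were below the ratio, the call of Mid1 being lost in edgeR without replicate 1, 2 or 4 (adjusted p = 0.161, 0.0701 and 0.0811, with 0.000165 to 0.204 over 16 alternatives) and without the replicate block (adjusted p = 0.0513), and Ftx, with 11.6% ± 3.43, was undecided. The genes lie at X:94188707-94212862 (Eif2s3x, ENSMUSG00000035150), X:18162575-18279936 (Kdm6a, ENSMUSG00000037369), X:152233020-152274535 (Kdm5c, ENSMUSG00000025332), X:13280970-13294052 (Ddx3x, ENSMUSG00000000787), X:103493556-103565696 (Jpx, ENSMUSG00000097571) and X:105079756-105117090 (Pbdc1, ENSMUSG00000031226) in mm10. For these 6 genes the log2 ratio over the 0.1 null ranged from 0.91 for Pbdc1, with a standard error of 0.11, to 2.68 for Eif2s3x, with a standard error of 0.09, and each exceeded the null in 4 of 4 replicates. In edgeR a null ratio of 0.2 ended the calls of Jpx and Pbdc1 (adjusted p = 0.905 and 0.480), and one of 0.05 those of Utp14a and Mid1 (adjusted p = 0.943 and 0.204).

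Calls above the ratio were more frequent in the constitutive escape list than among the other X genes (odds ratio 21, Fisher's exact test, two-sided, adjusted p = 0.000193 over 4 lists). The set test camera did not call the list, with an adjusted p of 0.947 at a preset correlation and an adjusted p of 0.956 with an estimated correlation. Camera ranked genes by their departure from equal alleles and not from the 0.1 ratio, so it asked another question than the calls. The counts adjusted over the list alone were also 6 above and 2 below. The median Xi share was 17.4% in the list and 0.0326% in the other X genes, and a permutation test of that difference, chosen after the data were seen, gave an adjusted p of 0.00364. The edgeR call of Jpx was lost without replicate 4 (adjusted p = 0.0776, with 0.000352 to 0.905 over 16 alternatives). Jpx overlaps Ftx on the opposite strand and Gm9670 and Gm14860 on the same strand, and the reads they share were not separated.

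**Figure D2:**
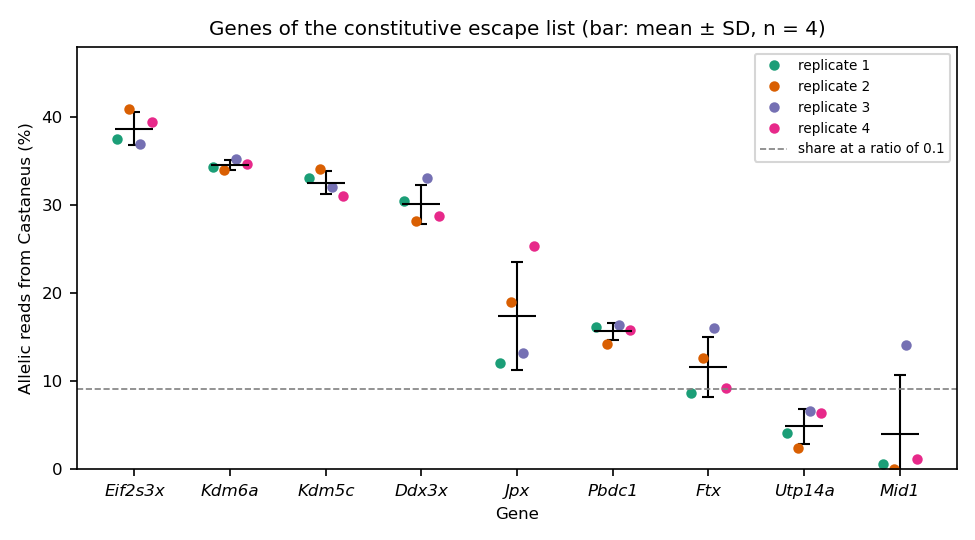
Share of allelic reads from Castaneus (vertical axis, percent) for the 9 tested genes of the constitutive escape list (horizontal axis), with 1 coloured point per replicate and black bars for the mean and SD of 4 replicates. The dashed line marks the share at an Xi to active X ratio of 0.1, which is 9.09%; Eif2s3x, Kdm6a, Kdm5c and Ddx3x lie far over it in each replicate, while Utp14a lies under it.

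The variable escape list holds genes known to escape in some tissues. Of its 15 genes 7 were tested, and 0 were above the ratio, 6 were below and Firre, a long noncoding RNA gene with 7.16% ± 2.46 of its reads from the Xi, was undecided. Slc6a8, with 21.6% ± 11.05 from Castaneus, was left out by its 0.869 RPKM, and without the RPKM minimum 12 genes of the list were tested, of which 0 were above and 9 below. Usp9x, which encodes a deubiquitinase, had 0.142% ± 0.0978 of its reads from the Xi, Uba1, which encodes the enzyme that activates ubiquitin, 0.173% ± 0.183, and 1810030O07Rik 4.14% ± 3.09 (SD, n = 4). Zrsr2, a splicing factor gene, had 0 Castaneus reads of 7797 over the 4 replicates, which allows a share of up to 0.0385% by counting error alone. The counts adjusted over the list alone, and those at an unadjusted p under 0.05, were also 0 above and 6 below in edgeR, and DESeq2's Wald test called 0 above and 5 below. The list did not pass against the other X genes (Fisher's exact test, two-sided, adjusted p = 1). The edgeR call of 1810030O07Rik was lost without replicate 1 (adjusted p = 0.0513) and without replicate 4 (adjusted p = 0.0624), in DESeq2's Wald test (adjusted p = 0.0843) and at a null ratio of 0.05 (adjusted p = 0.497), with 0.00115 as the lowest of 16 alternatives. Camera gave an adjusted p of 0.667 and an adjusted p of 0.846 with an estimated correlation.

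Immune genes of the X were mostly silent on the Xi, as were X genes at large. Of all X genes tested, Xist left out, 79.5% were below the ratio. Of the 28 genes of this list 22 were tested, and 16 were below the ratio, 3 above and 3 undecided, with the same counts adjusted over the list alone. The undecided genes were Cybb with 15.3% ± 11.8, Elf4 with 17.5% ± 12.2 and Dock11 with 28.4% ± 19.1 of their reads from Castaneus. Without replicate 4, 5 genes were above and 16 below. Msn, which encodes the cytoskeletal linker moesin, had 0.0196% ± 0.0150 of its reads from the Xi, Pim2, a kinase gene, 0.386% ± 0.469, P2ry10, a receptor gene, 0.126% ± 0.158, and Il2rg, which encodes the shared cytokine receptor chain, 1.16% ± 0.20 (SD, n = 4). The 3 genes above were Arhgef6 with 16.8% ± 3.92, Magt1, a magnesium transporter gene mutated in a human immunodeficiency, with 14.2% ± 4.72, and Btk, a B cell kinase gene, with 100% of a mean of 54 reads. In edgeR a null ratio of 0.2 ended the calls of Arhgef6 and Magt1 (adjusted p = 0.902 and 0.154), whose adjusted p was as low as 9.95e-11 and 2.17e-05 in other alternatives. Calls above were not detectably more or less frequent than among the other X genes (adjusted p = 0.712, Fisher's exact test, two-sided), and camera gave an adjusted p of 0.667 and an adjusted p of 0.775 with an estimated correlation. Btk had no C57BL/6 read among 216 over the 4 replicates, which allows a C57BL/6 share of up to 1.39% by counting error alone, and a larger one where several reads are copies of 1 molecule.

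Of the 10 X-linked genes of the NF-κB list, 7 were tested, and 6 were below the ratio and 1, Btk, above it. Btk had 100% of a mean of 54 reads from Castaneus, and whether these reads came from the Xi stays open. Ikbkg, which encodes the NEMO subunit of the IκB kinase, had 0.478% ± 0.364 of its reads from the Xi, Irak1, a kinase gene of receptor signalling, 0.0643% ± 0.0743, Tab3 0.173% ± 0.273 and Xiap, which encodes an inhibitor of apoptosis, 0.0172% ± 0.0344 (SD, n = 4). The counts adjusted over the list alone were the same. Calls above were not detectably more or less frequent than elsewhere on the X (adjusted p = 0.712, Fisher's exact test, two-sided), and camera gave an adjusted p of 0.667 and an adjusted p of 0.775 with an estimated correlation. Ikbkg overlaps G6pdx on the opposite strand.

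Over the whole chromosome 304 X genes were tested, of which 32 were above the ratio of 0.1, 241 below and 31 undecided (edgeR's quasi-likelihood test, Benjamini-Hochberg over X genes, FDR of 5%). Apart from Xist, 223 of 303 genes had a mean Xi share under 1% and 129 had no Castaneus read in any replicate. The genes below with the most reads were Rps4x, a ribosomal protein gene, with 0.0217% ± 0.00536 of its reads from the Xi, Msn, Huwe1, a ubiquitin ligase gene, with 0.0489% ± 0.0225, Flna, which encodes filamin A, with 3.13% ± 0.537, and Atrx, a chromatin remodeller gene, with 0.130% ± 0.0954 (SD, n = 4). Among the 31 genes above other than Xist, 18 were protein coding and 12 had Gm numbers or pseudogene names.

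Some of the genes above had more reads from Castaneus than from C57BL/6. Of the 31 genes 10 exceeded equal expression in edgeR's test, and 6 of them, Btk, Rpl36a, Gla, Fam220-ps, Gm6472 and Gm15190, had no C57BL/6 read in any replicate. Gla, which encodes the lysosomal enzyme alpha-galactosidase A (X:134588149-134601125), had 636 Castaneus reads over the 4 replicates, and Rpl36a (X:134585654-134588062), a ribosomal protein gene, 106. The pseudogene Gm8172 (X:69605496-69606245) had 99.96% ± 0.0478 of a mean of 4396 reads from Castaneus, and Gm14639 had 81.3% ± 14.6, Hnrnph2 79.4% ± 5.95 and Diaph2, a formin gene, 63.5% ± 4.91 (SD, n = 4). Gm14719 with 76.4% ± 16.4, Xlr4d-ps with 67.9% ± 9.71, Gm5637 with 55.1% ± 31.4 and Gm8822 with 53.4% ± 18.5 did not pass the test against equal expression. Processed pseudogenes resemble their parent genes in sequence, and how reads that match both were placed is not stated. An alternative chosen after the data were seen left out genes with Gm numbers or pseudogene names and genes that exceeded C57BL/6. It also left out the genes that differed between animals after division by the reads per molecule. Of the remaining 267 genes 12 were above, namely Slc10a3, Mtcp1, Atp7a and Trmt2b beside the 6 escape list genes, Arhgef6 and Magt1. On undivided reads, Arhgef6 and Magt1 did differ between animals.

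The Castaneus share of some X genes differed between the 4 animals. The chi-square test of alleles by replicates called 112 of 304 X genes when it was run on reads, and 4 when reads were first divided by the estimated number of reads per molecule, an alternative chosen after the data were seen. Cul4b, a ubiquitin ligase scaffold gene (X:38533274-38576196), had 100%, 100%, 99.8% and 0% of its reads from Castaneus in replicates 1 to 4, and Mbnl3, a splicing regulator gene (X:51117269-51206532), 100%, 100%, 99.3% and 0%. Dock11, a Cdc42 exchange factor gene (X:35888832-36076562), had 40.6%, 38.5%, 34.5% and 0%, and Elf4, an ETS transcription factor gene (X:48411046-48463132), 18.6%, 22.9%, 28.3% and 0.197%. Fmr1 had 4.73% in replicate 2 and at most 0.104% in each of the others, and was called on reads only. The total level of Cul4b was 21.7 ± 2.02 RPKM and that of Elf4 28.6 ± 1.71 RPKM (SD, n = 4). For Dock11 the C57BL/6 part of the RPKM had a coefficient of variation of 33.5% over the animals and the total one of 8.93%. The edgeR calls of Cul4b and Mbnl3 above the 10% ratio were lost without replicate 1 (adjusted p = 0.109 and 0.105) and without replicate 3 (adjusted p = 0.0796 and 0.0774), and Dock11 and Elf4 were called above without replicate 4 (adjusted p = 1.16e-06 and 1.75e-06). Dock11 was also called above without the replicate block (adjusted p = 0.0179), at a null ratio of 0.05 (adjusted p = 0.0287) and on the molecule scale (adjusted p = 0.00165). Over 16 alternatives the adjusted p reached 0.109 for Cul4b, 0.105 for Mbnl3, 0.458 for Dock11 and 0.957 for Elf4.

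**Figure D3:**
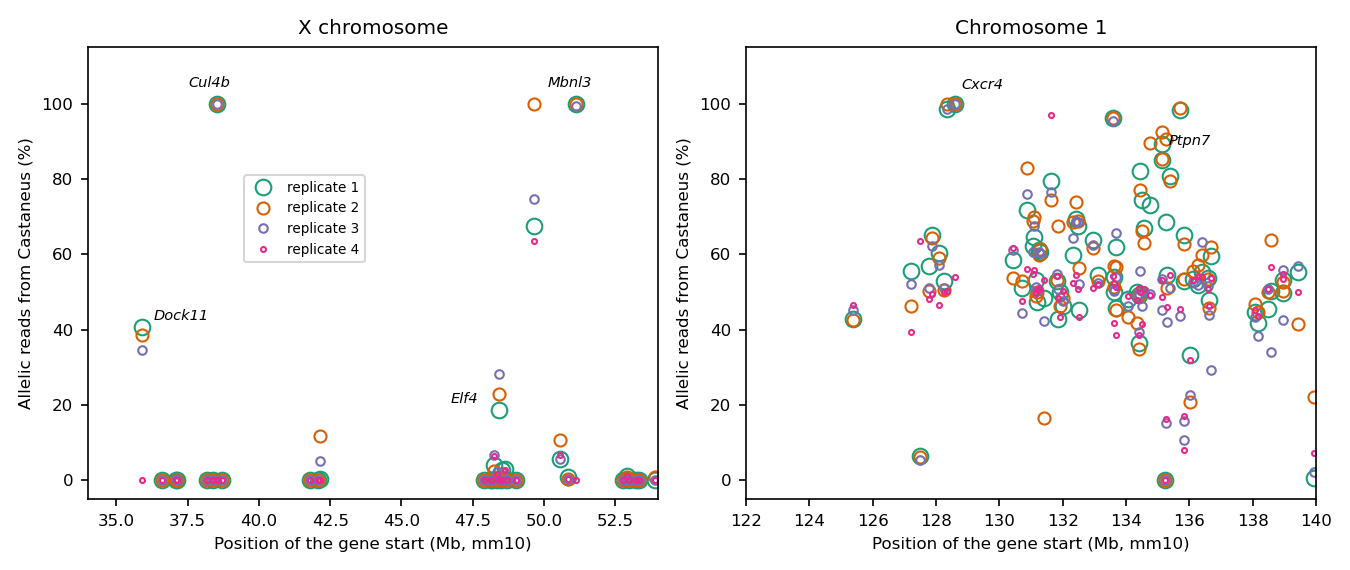
Share of allelic reads from Castaneus (vertical axes, percent) by gene position (horizontal axes, Mb) on a part of the X chromosome (left) and of chromosome 1 (right, genes with at least 200 reads), 1 ring per gene and replicate. On the X, Cul4b and Mbnl3 have rings of replicates 1 to 3 near 100% and of replicate 4 at 0%, and on chromosome 1 the rings of Cxcr4 lie at 99.9%, 100%, 99.8% and 54.1%.

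No relation between the Xi share and the distance to Xist was detected. Genes on either side of Xist, from Ddx3x at X:13280970 to Kdm5c at X:152233020, were above the ratio, and so was Jpx beside Xist. Across 303 genes, the Spearman correlation of the Xi share with the distance to Xist was -0.0224 (permutation p = 0.696, adjusted p = 0.696) and the Pearson correlation was -0.0586 (permutation p = 0.310, adjusted p = 0.620), over 2 relations computed. These are correlations across genes, which are not independent replicates.

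On the autosomes, unequal read numbers from the 2 alleles were common. Of 10268 autosomal genes tested, 1241 had more reads from Castaneus and 1548 more from C57BL/6 (edgeR's quasi-likelihood test, FDR of 5%), and 877 of these genes differed by at least 2-fold. The 5 genes that leaned furthest to Castaneus, Gm10076, Gm15484, Rpsa-ps9, Rpl13a-ps1 and Rpl38-ps2, had 100% of their reads from Castaneus, and the 5 that leaned furthest to C57BL/6, Gm4204, Gm4149, Rpl27-ps2, Rpl37rt and Gm8730, had at most 0.0242%. Of these 10 genes 8 are annotated as processed pseudogenes, Rpl37rt as a transcribed processed pseudogene and Gm10076 as a long noncoding RNA. Among the 189 calls with an absolute log2 ratio of at least 5, 111 had Gm numbers or pseudogene names, which is 58.7%, against 8.72% of all autosomal genes tested. Mapping bias of single genes was not tested, so unequal reads need not be unequal expression. Strain and parent of origin cannot be told apart in this cross outside genes known to be imprinted. The split between the parents moved from 44.5% of calls on the Castaneus side to 52.4% with TMM factors, and without replicate 4 there were 982 genes higher from C57BL/6.

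The cells expressed T cell and NF-κB pathway genes at high levels. The 16 NF-κB component genes had a median of 39.8 RPKM, with Nfkbia, the inhibitor gene that NF-κB itself switches on, at 200.4 ± 16.4 RPKM, Nfkb2 at 150.2 ± 3.95, Tnfaip3 at 68.1 ± 9.88 and Ikbkg, the lowest, at 5.78 ± 0.923 (SD, n = 4). The 18 T cell activation genes had a median of 34.1 RPKM, with the transcription factor genes Irf4 at 167 ± 11.6 and Nr4a1 at 150.2 ± 8.43, the costimulatory receptor gene Tnfrsf4 at 89.7 ± 5.47 and the cytokine gene Il4 at 0.0280 ± 0.0323. The 10 genes of resting T cells had a median of 21.7 RPKM, with the homing receptor gene Ccr7 at 719.6 ± 41.0, Tcf7 at 245.3 ± 34.6 and Foxp1 at 28.8 ± 3.55. Among 10000 random lists of the same size these medians ranked at percentiles 100, 100 and 99.9.

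The 11 proliferation genes had a median of 6.90 RPKM (percentile 86.9), with the replication genes Pcna at 23.9 ± 1.08, Mcm7 at 15.5 ± 0.489 and Mcm4 at 10.6 ± 1.18, and the cyclin gene Ccnb1 at 0.304 ± 0.0999 (SD, n = 4). The 14 genes of proteins that act with Xist had a median of 18.6 RPKM, with Hnrnpk at 78.8 ± 4.11, Pcgf5 at 48.1 ± 3.66, Yy1, a factor that tethers Xist RNA, at 39.3 ± 4.41 and Pcgf3 at 3.58 ± 0.341. Percentiles describe these libraries and are no test, and with the random lists drawn from genes of at least 1 RPKM the proliferation list fell to percentile 52.4.

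Markers of T cells were high and those of most other cells low. The 9 T cell genes had a median of 42.4 RPKM, with Lck at 65.5 ± 2.99, Zap70 at 57.5 ± 5.57, Cd8b1 at 49.7 ± 2.25 and Cd3g at 8.79 ± 1.84 (SD, n = 4). The median was 0.955 RPKM for 8 B cell genes, 0.742 for 11 myeloid genes, 0.0895 for 5 NK cell genes and 1.22 for 5 erythroid genes. Ighm, which encodes the IgM heavy chain, was at 31.2 ± 3.37, while Cd79a was at 2.37 ± 1.06, Cd79b at 2.09 ± 0.668 and Cr2 at 0.205 ± 0.0618. Of the myeloid list Lyz2 was at 41.3 ± 24.6, S100a8 at 28.3 ± 19.5, Cd68 at 14.6 ± 3.20 and Siglech at 0.00855 ± 0.0171. Of the NK cell list Eomes was at 3.93 ± 0.409, Klre1 at 0.358 ± 0.337, Ncr1 at 0.0895 ± 0.0993 and Klrb1c at 0.0633 ± 0.0494, and of the erythroid list Hbb-bs at 2.05 ± 1.24, Hba-a1 at 1.27 ± 0.714 and Hbb-bt at 1.22 ± 0.812.

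The median RPKM of 521 X genes was 0.784 ± 0.0182 times that of 16192 autosomal genes (SD, n = 4), in a range of 0.761 to 0.805 over the replicates. Both medians were taken over genes with a mean of at least 0.1 RPKM.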

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

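The tests of the patterns in this part, and the bounds set for them, were chosen after the results were seen. Among 89 groups of 4 values 11 had a replicate far from the other 3, where chance gives about 1 in 20 groups, or 4.45. In 4 of the 11, Xiap, Gm8730, Rpl37rt and Siglech, the other 3 replicates are at 0, which fixes the gap at 1, so the 11 are not set against that number.

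The Castaneus share of Cul4b in replicate 4 (0%, against 99.8% to 100% in the others) had a gap of 0.998 of the whole range, that of Mbnl3 in replicate 4 a gap of 0.993, and that of Dock11 in replicate 4 a gap of 0.851. Together with Elf4 these genes lie between X:35888832 and X:51206532, where 15 of 26 tested genes stayed under 1% in 4 of 4 replicates. Expression from the Xi added in some animals is argued against, since for 2 of 2 genes, Dock11 and Elf4, the C57BL/6 part of the RPKM varied more between animals than the total (coefficients of variation of 33.5% against 8.93% and 18.3% against 5.98%), while for Cul4b and Mbnl3 the shares fix this outcome. Sampling noise from duplicate reads is argued against only by the chi-square test that picked these 4 genes among 304 X genes. After division by the reads per molecule it gave an adjusted p of at most 0.00076 for each gene. Chromosome segments that differ between the mothers' chromosomes, so that some maternal alleles look like Castaneus, are a candidate explanation: on the autosomes, without the X genes that prompted the test, 65 of 8186 genes differed between animals on the molecule scale, and 33 of them had another within 3 Mb, against a median of 15 and a highest value of 33 in 10000 random gene sets (permutation p = 0.0002). Which variants the maternal chromosomes carry was not analysed here, and no biological explanation beyond expression from the Xi was tested.

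The other replicates that stood apart were the Castaneus shares of Fmr1 in replicate 2 (gap 0.978), Huwe1 in replicate 1 (0.840), Il2rg in replicate 1 (0.917), Mid1 in replicate 3 (0.915), Xiap in replicate 2 (1), Gm8730 in replicate 3 (1) and Rpl37rt in replicate 4 (1), and the RPKM of Siglech in replicate 4 (1). Mid1 had 14.1% from Castaneus in replicate 3 and at most 1.20% in each of the others, while Huwe1 and Xiap stayed under 0.1% in every replicate. In data that no comparison used, Erdr1, which the files place on the Y chromosome, had 105 allelic reads over the 4 replicates of female mice, more than the 3 that a count of 0 allows. Of these, 47, 16, 20 and 18 in replicates 1 to 4 came from the C57BL/6 allele, that of the mothers, who carry no Y chromosome. These reads are therefore no evidence of a Y chromosome in the samples. Gm28598, Gm20804, Gm20803 and Gm29342, also placed on the Y, had 0 allelic reads.

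Swaps of the 2 alleles within replicates gave 8 distinct splits, too few for a share under 0.05. The real split gave 2789 autosomal calls and the highest of the others 0. For X genes called below, a split and its mirror image differ, since the null ratio is 0.1. The real split gave 241, its mirror image, with the alleles swapped in every replicate, 7, and the highest of the others 1. In both counts 1 of the 8 splits, the real one, gave as many.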

How the results depend on the processing

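Alternatives named here as added were chosen after the data were seen, and the cause of a change was not tested unless the alternative's own construction shows it. The count of X genes above the ratio was 26 to 45 over the planned null ratios, filters, scalings and tools. It was 12 without genes that differ between animals on the molecule scale, exceed C57BL/6 reads or have Gm or -ps names (added). Leaving out 1 replicate gave 30 to 34. The binomial calls per replicate asked for a lower limit of the Xi share over 0.01 and not for the 0.1 ratio. They took 58 genes in at least 3 of 4 replicates, 30 of the 32 genes among them. Flna (3.13%) and Med14 (3.27%), which the main test called below, were also taken. The count below was 224 to 285, 288 with both a minimum of 10 reads and no RPKM minimum, or 230 to 242 with 1 replicate left out. Without the replicate block there were 35 X genes above, 243 below, and 945 and 1124 autosomal genes. Autosomal genes higher from C57BL/6 numbered 982 to 1618 and those higher from Castaneus 856 to 1273 with 1 replicate left out, lowest without replicate 4 for the first and without replicate 1 for the second. DESeq2's Wald test called 1662 and 2174, and the molecule scale (added) 1492 and 1979. The median autosomal log2 ratio moved from -0.04 to 0.01 with TMM factors.

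The Xi share of 3.52% was 7.04% as the mean and 0% as the median of genes, 2.30% without the constitutive escape list, 2.65% without Gm, Rik and -ps genes, and, as added alternatives, 0.931% without the genes above, 2.65% without the genes whose Castaneus reads exceed C57BL/6 reads and 16.2% with Xist. With 1 replicate left out it was 3.42% to 3.68%. The escape list lost its call in camera (adjusted p = 0.947 at a preset and an adjusted p of 0.956 with an estimated correlation). X genes that differed between animals fell from 112 to 4 on the molecule scale (added). The correlation with the distance to Xist became 0.00247 without the genes above within 1 Mb of Xist. With genes of at least 1 RPKM the X to autosome ratio was 0.750, and with log2(RPKM + 1) it was 0.837; the percentiles became 99.56 for genes of resting T cells, 52.4 for proliferation, 99.67 for Xist factors, 99.99 for T cells, 0 for B cells, 0 for myeloid cells and 0.03 for erythroid cells, and for Xist factors 99.93 to 99.98 with 1 replicate left out.

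For 46 named X genes, 708 of 733 values kept their direction and side of the threshold, 16 lost and 5 gained a call, and 4 changed direction: at a null ratio of 0.2, Elf4 (log2 ratio over the null -0.289), Magt1 (-0.293) and Pbdc1 (-0.0857), and at 0.05 Utp14a (0.0172), none of them past the threshold. For 17 named autosomal genes 215 of 221 values kept both, and the 6 others were calls of H13. At an estimated 7.19 to 22.6 reads per molecule, genes of few reads rest on few molecules.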

Other observations

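The tests of the hypotheses in this part were chosen after the results were seen. Several X genes were below the 10% ratio and still gave Xi reads in each animal. Among genes with at least 500 allelic reads, 10 genes called below had a mean Xi share of at least 1% and Castaneus reads in 4 of 4 replicates. They include Gprasp1, a receptor sorting gene, with 6.32% ± 1.78, Tbl1x, which encodes a corepressor subunit, with 5.68% ± 1.39, Med14, a Mediator subunit gene, with 3.27% ± 0.817, Flna with 3.13% ± 0.537 and Il2rg with 1.16% ± 0.20 (SD, n = 4). Msn, for comparison, had 0.0196% ± 0.0150. At a null ratio of 0.05 the count of genes above was 45.

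The 11 genes of the myeloid list had a median of 0.891, 1.14, 0.609 and 0.640 RPKM in replicates 1 to 4. Of its members, chosen after their values were seen, Lyz2 was at 44.7, 74.4, 27.2 and 18.8 RPKM, S100a8 at 29.9, 54.9, 17.3 and 10.8 and S100a9 at 16.7, 23.0, 8.41 and 5.45, while Cd3e, of the T cell receptor complex, was at 42.4 ± 2.30 (SD, n = 4). The highest of these myeloid values were in replicate 2, which also had the most reads per molecule, 22.6, and no difference was tested. The cytokine gene Il17a was at 88.7, 27.4, 21.5 and 13.1 RPKM.

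On chromosome 1, 17 of 43 genes between 1:127868773 and 1:135833342 differed between animals on the molecule scale. Over all 25 testable genes of the first part, up to 1:133610291, the median Castaneus share was 59.7%, 59.8%, 60.3% and 51.0% in replicates 1 to 4, and over the 10 from 1:134455531 on it was 77.6%, 78.3%, 47.8% and 49.0%. Over the 8 and 9 genes of these parts that differed, it was 66.3%, 68.7%, 65.5% and 52.6%, and 80.7%, 79.5%, 49.4% and 49.2%. The 8 testable genes between these parts, none of which differed, had medians of 49.6%, 47.1%, 49.8% and 48.3%. The limits of the parts were chosen after the values were seen. Cxcr4, the chemokine receptor gene (1:128588199-128592293), had 99.9%, 100%, 99.8% and 54.1%, while Ctse of the same part went the other way, with 79.4%, 74.4%, 76.5% and 97.1%. The phosphatase gene Ptpn7 (1:135132700-135145317) had 85.0%, 85.2%, 53.4% and 53.2%. On chromosome 18, 6 of 12 genes between 18:5591860 and 18:10610352 differed, among them Kif5b with 52.4%, 50.3%, 90.4% and 90.8%.

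A second pattern is the 7 X genes above the ratio with over 99% of reads from Castaneus: Btk, Rpl36a, Gla, Fam220-ps, Gm6472, Gm15190 and Gm8172. Expression from the Xi added to that from the active X needs C57BL/6 reads. That 6 of these 7 genes had none does not test it, since the genes were selected for a share that leaves almost none. For the genes with the most reads the values themselves argue against it, provided that C57BL/6 reads could be assigned there. Gla had 0 C57BL/6 reads of 636, Gm6472 0 of 688 and Gm8172 a mean of 1.5 of 4396. For the other genes, which have fewer reads, it stays open. Reads of similar genes elsewhere may account for part of them, since 4 of the 7 have Gm numbers or pseudogene names against 23 of the other 296 X genes (Fisher's exact test, p = 0.00147, after an earlier test on the 10 genes over equal expression gave p = 0.000719). A maternal X segment that is not C57BL/6 stays open for Btk, Rpl36a and Gla, which are neighbours: 3 of the 7 genes had another within 1 Mb, against a median of 2 in random sets of X genes (permutation p = 0.162), so 7 genes are too few to settle it. Hnrnph2, beside Gla, had 79.4% from Castaneus with a mean of 46.5 C57BL/6 reads. Trmt2b (X:134222339), between Cstf2 and Btk, had 42.5% ± 8.21 and was called above. Cstf2 (X:134059187) and Armcx3 (X:134756595) had 0%. This does not show where such a segment would end, since only some maternal alleles in it need look like Castaneus.

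A further pattern is the autosomal genes with 20 to 39 reads seen from 1 allele only. Expression from 1 allele is argued against as the whole cause, because the share of such genes differed between replicates by 70.6 percentage points at the same number of reads. Copies of few starting molecules may account for part of it, but the tests did not settle this. At least 10% of the other allele was seen in the other replicates for 69.8% of such genes, where over 70% had been set as the mark for copies. By replicate this value was 61.0%, 81.9%, 68.5% and 26.2% in replicates 1 to 4. In an earlier test of the same explanation, genes seen from 1 allele in both of 2 replicates showed the same allele in 80.2% of 434 cases. Copies of equally active alleles would give 50%. The lowest of the 6 pairs was 67.7%, for replicates 2 and 3, and the highest 100%, for replicates 3 and 4.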
